A study of Mus musculus with 12 samples.

How the data were processed

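The deposited files hold unfiltered counts of UMIs per gene and droplet, made by the authors with Cell Ranger and the mm10 genome per the submitters' processing notes, and with Cell Ranger 4 per the file headers. Each of the 12 libraries listed 32285 genes and 737280 barcodes. The labels' protocols describe sorting of live CD45-positive cells after collagenase digestion of the tumours and 5' 10x libraries. Everything below was computed from those counts. Gene identifiers were matched to the mm10 annotation at hand, and 32158 of them (99.61 percent) had a match.

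Barcodes with at least 1000 UMIs and 500 genes numbered 81976, and 3875 of them were removed because mitochondrially encoded genes held 10 percent or more of their UMIs. The 78101 kept cells held 69.6 to 92.7 percent of the UMIs of their library. Doublets were predicted per library from 2 simulated doublets per cell and the 50 nearest neighbours of each cell, and the cells with the highest scores were removed at a rate of 0.8 percent per 1000 cells, which took out 4.02 to 7.21 percent of a library and 4169 cells in all. Cells were log-normalized, reduced to 30 principal components of 2000 variable genes and clustered by Leiden on a graph of 20 neighbours at resolution 1, without any batch correction. This gave 31 clusters, and 43 after the T and NK clusters were clustered again, 20 of them of T and NK cells. A cluster was named from its 10 leading genes and from markers found in at least 20 percent of its cells, with marker genes fixed before the data were examined. The names were rebuilt here and may differ from those of the study. A cluster stayed unnamed where its median depth was low, where most of its cells were predicted doublets or where its leading genes belonged to several types. T cell clusters that held both CD8 and CD4 cells, or that were led by NK or cell cycle genes, stayed out of the CD8 and CD4 classes. Cluster L8, led by Ifng, Ccl4 and Xcl1, was left unassigned as well, although Cd8a was found in 87.79 percent of its cells and Cd4 in 1.67 percent.

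For each class the counts were summed per library, and libraries with fewer than 20 cells of the class were left out with their partner in the genotype comparisons. Genes were tested with edgeR's quasi-likelihood F test (robust, TMM factors, filterByExpr, Benjamini-Hochberg adjusted p under 0.05, two-sided). The genotype test used a block for the 6 conditions of treatment and day, the day test a block for the 6 groups, and the antibody tests a term for day beside the groups. The antibody contrast was the mean of both antibodies minus the control. Standard errors were taken from the log2 fold change and the F statistic. Cell numbers of 13 classes were tested in the same way with all compared cells as library size. An exact permutation of the shares for the antibody comparisons was not run, since that design cannot reach a p under 0.05. State genes of macrophages were tested by an exact sign flip over the 6 pairs (64 flips, smallest two-sided p 0.03125). The tests, the samples in each fit, the 27 gene lists, the markers and the rule for named genes were fixed before the data were examined.

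The genes named are the 10 largest rises and 10 largest falls past the threshold in each comparison, without receptor and immunoglobulin segments, unnamed gene models, ribosomal protein genes, haemoglobins, Xist and Tsix. To these were added genes from a list of 20 core genes per compartment, whatever their test, and the members with the smallest p of each list described. Not every core gene is named in each comparison, so that a core gene left out there may still have moved. A single gene of that core list is not reported here. Where a group had 0 counts, the fold was bounded by a floor of 3 counts over the group, which covers counting error only. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Over 18 comparisons and 435 list tests camera called 136, fry called 30 as moving one way and 125 as changing in either direction, and 3 calls held with an estimated correlation. Those 3 were the inflammatory list in NK cells by genotype, the B cell list in the macrophage/monocyte interaction, and the haemoglobin list between the antibodies in macrophage/monocyte cells.

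The scripts were tested on simulated data with 200 changed genes. For genotype in macrophage/monocyte cells, over 12894 genes, 64.6 percent of changes of 1.5-fold, 88.2 percent of 2-fold and 98.4 percent of 4-fold changes were recovered. For genotype in CD8 T cells (7005 genes) these were 53.3, 95.4 and 98.3 percent, and in conventional CD4 T cells (5606 genes) 9.5, 38.2 and 93 percent. For antibody in wild-type macrophage/monocyte cells (12851 genes) they were 31.2, 67.1 and 92.1 percent, and for antibody in wild-type CD8 T cells (7049 genes) 8.2, 50 and 98.4 percent. For antibody in knockout conventional CD4 T cells (5047 genes) they were 3.3, 17.4 and 73.8 percent. By genotype, false calls made up 6.82 percent of calls in macrophage/monocyte cells, 4.38 percent in CD8 T cells and 8.39 percent in NK cells. With 200 changed genes the simulation does not bear on a count as large as the 3113 called by genotype in macrophage/monocyte cells. DESeq2, RLE factors, no count filter, deeper cells, kept doublets, other class limits, other terms in the model and the leaving out of each library or pair served as alternatives, and fits without genes near Bhlhe40, on thinned counts, on single days, on single antibodies, without receptor segments and without a length trend were added later. The comparison of anti-CTLA-4 with control in conventional CD4 T cells of wild-type tumours and its interaction were added because no wild-type anti-PD-1 library held 20 such cells. T cell receptor sequences were not used here. The work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.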

Results

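Gene expression was measured by droplet single-cell RNA sequencing (10x 5' chemistry) in sorted live CD45-positive cells of an MCA sarcoma, a carcinogen-induced mouse tumour line transplanted under the skin of C57BL/6 females. The hosts were wild-type or lacked Bhlhe40, a transcription factor of activated lymphocytes and macrophages. Wild-type and knockout refer below to the host, also where tumours are named. They received an isotype control antibody, anti-PD-1 or anti-CTLA-4, and tumours were taken on day 9 or day 11. The 12 libraries fell into 6 groups of 2, with 1 library per genotype, treatment and day, so that each knockout library had 1 wild-type library of the same treatment and day. Wild-type libraries held 31705680 UMIs (control, day 9), 38658515 (anti-PD-1, day 9), 29535774 (anti-CTLA-4, day 9), 64452836 (control, day 11), 48126631 (anti-PD-1, day 11) and 42135676 (anti-CTLA-4, day 11). Knockout libraries held 49405904, 47455525, 46871892, 64885822, 78330118 and 72815516 UMIs in the same order, more than the wild-type partner in all 6 pairs. After filters on depth, mitochondrial share and predicted doublets, 73932 cells were compared, from 4826 to 8356 per library. The median cell had 2945 to 7772.5 UMIs and 1283 to 2238 genes. The labels do not say whether the libraries came from separate animals or from pools, so the p-values measure the spread between these libraries.

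Bhlhe40 (mm10 chromosome 6, 108660629 to 108666925) was examined first, as the targeted gene. Its mean in macrophage/monocyte cells was 45.2 ± 22.5 CPM (counts scaled to a common library total) in wild-type and 2.10 ± 0.754 CPM in knockout libraries (SD, n = 6 each). CD8 T cells held 220 ± 64.9 and 37.2 ± 11.6 CPM, conventional CD4 T cells 528 ± 294 and 73.9 ± 17.7 CPM, and NK cells 171 ± 30.7 and 19.7 ± 6.76 CPM in the same order. Bhlhe40 was lower in the knockout library in 29 of 30 combinations of pair and class, and the exception was Treg cells of the anti-CTLA-4 pair of day 9 (wild-type 19.9, knockout 64 CPM). These were 1 and 3 counts in 16 cells each, under the minimum of 20 cells. The log2 fold change of knockout over wild-type by edgeR was -4.35 (SE 0.40, adjusted p = 0.00142) in macrophage/monocyte cells and -3.17 (SE 0.15, adjusted p = 6.36e-18) in NK cells. Where in the gene the remaining knockout reads lie is not known from gene counts. Mean Bhlhe40 was lower in every class examined. A change within a class may thus follow from its loss there or in other cells, which this design cannot tell apart.

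**Figure D1:**
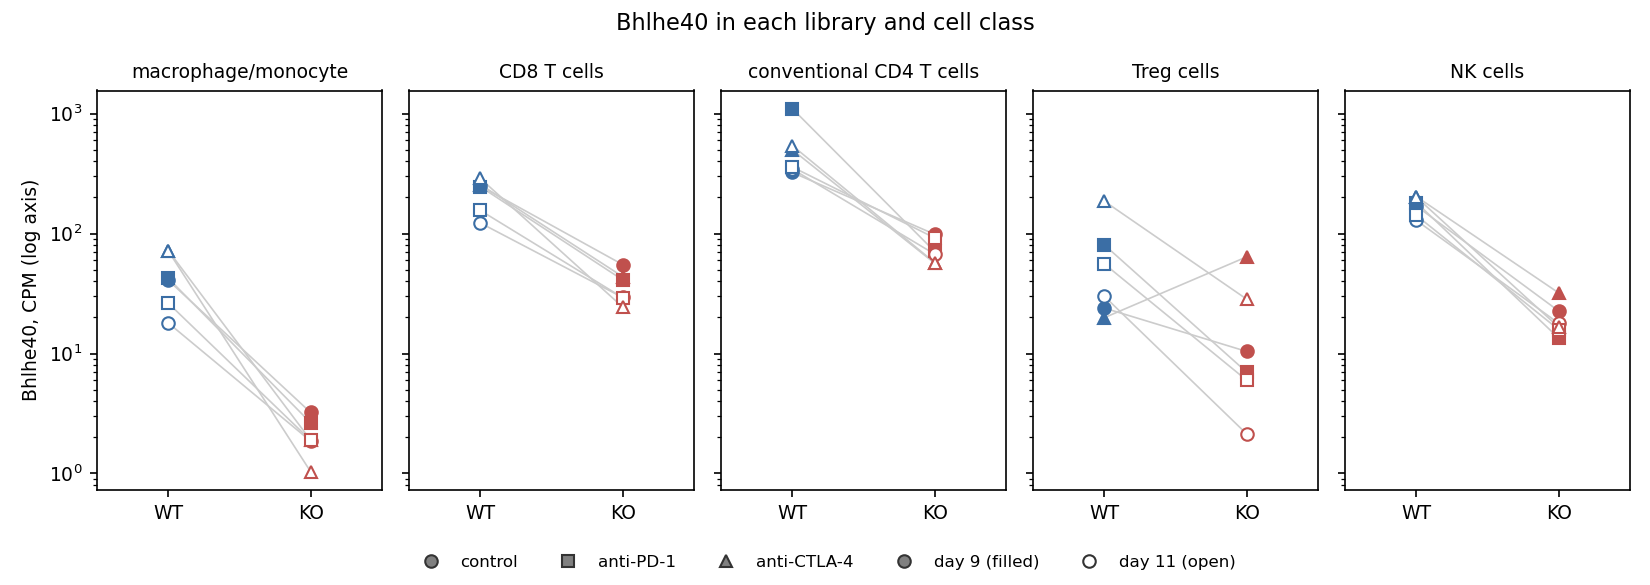
Bhlhe40 in CPM (vertical axis) of each library by cell class and genotype, with lines joining the libraries of 1 treatment and day and symbols for treatment and day. Knockout libraries lie below their wild-type partner in 29 of 30 combinations.

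Macrophage/monocyte cells of knockout and wild-type tumours were compared to ask how myeloid cells of the tumour differ in hosts without Bhlhe40. The comparison ran over 6 pairs of libraries with 24416 knockout and 19962 wild-type cells. The knockout cells had more RNA for receptors and lipid carriers of resident-type tissue macrophages, among them Cx3cr1, the fractalkine receptor, Apoe, a lipid carrier, Trem2, a lipid-sensing receptor, C1qa, a complement part, and Vsig4, a complement receptor. They had less of Nos2, which makes nitric oxide, of Cd274, the ligand of PD-1, and of interferon-induced GTPase genes such as Gbp4 and Irgm1. Fpr2, a receptor for formylated peptides, and Il27, a cytokine subunit, also fell. Of 27 genes of glycolysis and hypoxia 6 fell, among them Eno1, Hk2 and Gapdh. Gapdh lies near Bhlhe40 on chromosome 6, as does the neuronal enolase Eno2, which rose.

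The edgeR test called 3113 of 13078 genes at an adjusted p under 0.05, with 1508 higher and 1605 lower in knockout cells, and 5030 genes had an unadjusted p under 0.05. Fits on day 9 alone gave 3953 called genes and on day 11 alone 11 (3 pairs each), while a fit over all 12 libraries with a genotype effect per day gave 2257 at day 9 and 359 at day 11. The largest rise was that of C1rb, which had 337 counts in knockout and 0 in wild-type cells, at least 72.1-fold higher against a floor of 3 counts over the wild-type group. Further large log2 rises were those of Pianp (6.41, SE 0.19), Eno2 (5.22, SE 0.45), Rasgrp3 (3.92), Vsig4 (3.67, SE 0.80, edgeR adjusted p = 0.0114), Kcnip3 (3.54), Rab3b (3.17), Fcrls (2.92), Cspg4 (2.84, 5 of 6 pairs) and H60b (2.65). The largest falls beside Bhlhe40 were those of Klra3 (-6.68), Clec9a (-4.31, SE 0.25), Clec1b (-3.59), Gzme (-3.48), Wnk2 (-3.09), Gp6 (-3.08), Gzmg (-3.04), Wfdc21 (-2.96) and Cd200 (-2.85). All of these but Cspg4 moved one way in 6 of 6 pairs. Klra, Klr, Clec and Gzm genes belong to families that may share reads, which was not tested here. C1rb, Pianp, Eno2, Klra3, Clec9a and Clec1b lie near Bhlhe40 on chromosome 6, and 89 of the 284 genes tested within 25 Mb of Bhlhe40 were called.

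Of the core macrophage genes, Nos2 fell by 2.25 log2 units (SE 0.42, edgeR adjusted p = 0.0133) and Cd274 by 1.17 (SE 0.14, adjusted p = 0.00131), each in 6 of 6 pairs. H2-Ab1, an MHC class II chain, fell by 0.43 and Ly6c2, a monocyte marker, by 0.42, each in 5 of 6 pairs. Rises were found for Spp1 or osteopontin (1.40, SE 0.29), Cx3cr1 (1.19, SE 0.13), the folate receptor Folr2 (1.10, SE 0.22), Apoe (1.06, SE 0.14), Trem2 (0.65, SE 0.08), C1qa (0.64, SE 0.13), Ccr2 (0.42) and the mannose receptor Mrc1 (0.42, 5 of 6 pairs). Not past the threshold were Arg1 (-0.89, edgeR adjusted p = 0.207, 4 of 6 pairs lower), Il10 (0.81, adjusted p = 0.0731), Cxcl9 (-0.36), Il1b (-0.22), Maf (-0.20) and Cxcl10 (0.01). With a genotype effect per day, Cxcl9 stood at -0.87 at day 9 and 0.16 at day 11 (edgeR adjusted p = 0.0194 and 0.642). H2-Ab1 stood at -0.73 and -0.13 (edgeR adjusted p = 0.00791 and 0.575). Neither differed between the days past the threshold (edgeR adjusted p = 0.350 and 0.381). Cd274, Cx3cr1, Apoe and Trem2 were called at both days, and Mrc1 at day 9 alone. Nos2, Spp1, Folr2, C1qa, Ccr2 and Ly6c2 were called at neither day. Nos2 stood at -2.26 at day 9 and -2.25 at day 11 (edgeR adjusted p = 0.0811 and 0.151). Mean Apoe was 4504 CPM in wild-type and 8847 CPM in knockout libraries.

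**Figure D2:**
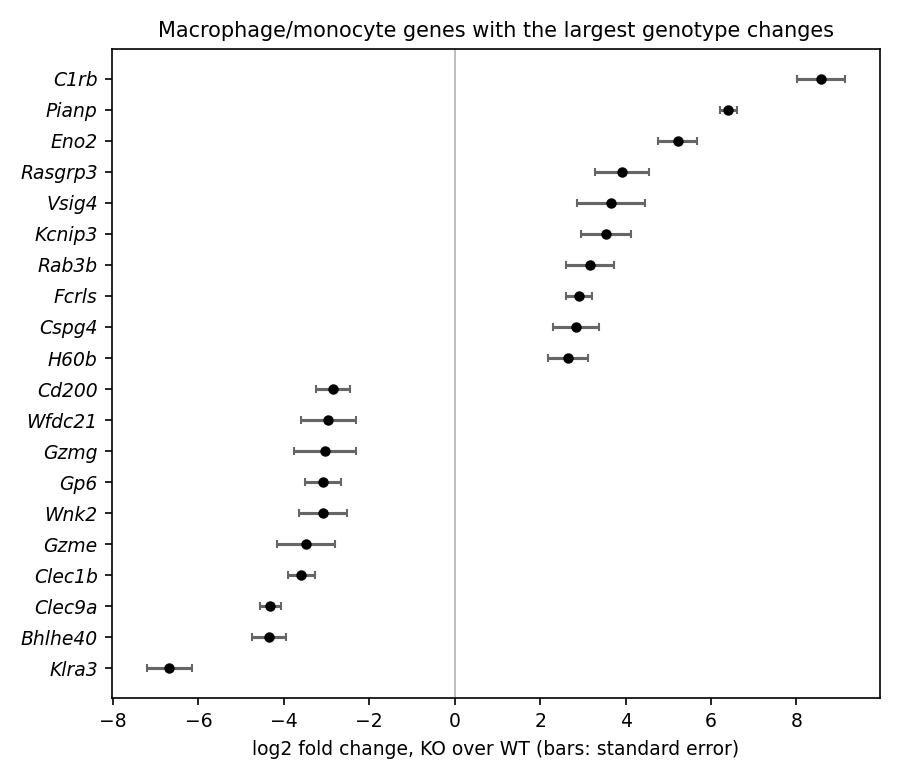
Log2 fold change of knockout over wild-type (horizontal axis, bars are standard errors, 6 pairs of libraries) for the 10 largest rises and 10 largest falls called in macrophage/monocyte cells. C1rb had 0 counts in wild-type cells, so that its point is a fitted value and its fold is at least 72.1.

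Of 31 measured genes in the list of tissue macrophages, 15 rose and 2 fell over all genes and 16 rose and 2 fell when adjusted over the list alone, among them Fcrls, Cx3cr1 and Apoe (camera adjusted p = 5.86e-09; adjusted p = 0.522 with an estimated correlation). Of 39 genes of the interferon-gamma response none rose and 23 fell by either adjustment, among them Gbp4 (-1.17), Irgm1 (-0.65) and Batf2 (-0.70) (camera adjusted p = 3.55e-12; adjusted p = 0.821 with an estimated correlation). The list of inflammatory macrophages (26 measured) had 1 rise and 5 falls by either adjustment, with Fpr2 (-1.44), Il27 (-0.74) and Acod1 (-0.61) (camera adjusted p = 0.00168; adjusted p = 0.865 with an estimated correlation). Of 27 genes of glycolysis and hypoxia 6 fell and 0 rose by either adjustment, with Gapdh (-0.56), Eno1 (-0.77) and the hexokinase Hk2 (-0.76) (camera adjusted p = 0.000479; adjusted p = 0.865 with an estimated correlation). Of 40 genes of the cell cycle 6 rose over all genes and 3 when adjusted over the list alone, with Tyms (0.68), Gins2 (0.55) and Cenpa (0.52), at a camera adjusted p of 2.39e-05 and an adjusted p = 0.865 with an estimated correlation. The T helper 1 list had 1 rise and 5 falls over all genes, and 1 rise and 7 falls when adjusted over the list alone (camera adjusted p = 0.000986; adjusted p = 0.821 with an estimated correlation). Its fallen members included Bhlhe40 itself and Il12rb1 (-1.29), a receptor for interleukin 12, and its risen member was Cxcr3 (1.12). Serpinb9 (-1.03), a protease inhibitor, and Gzmf (-2.49) led the list of T cell effectors, which had 1 rise and 6 falls over all genes, and 1 and 7 when adjusted over the list alone (camera adjusted p = 0.0223; adjusted p = 0.865 with an estimated correlation).

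Genes of other cells and of RNA quality moved with genotype in these cells as well. Of 14 markers of tumour cells and fibroblasts 8 rose and 0 fell by either adjustment, among them Timp1 (2.16), Sparc (0.79), Col1a1 (0.80) and Col3a1 (0.57), at a camera adjusted p of 3.55e-05 and an adjusted p = 0.821 with an estimated correlation. Of 13 mitochondrially encoded genes 10 fell by either adjustment, such as mt-Nd4 (-0.58) and mt-Co1 (-0.59), at a camera adjusted p of 0.000204 and an adjusted p = 0.821 with an estimated correlation. Of 15 general macrophage markers 6 rose over all genes and 9 when adjusted over the list alone, among them Cd68 (0.50) and Lyz2 (0.33), with a camera adjusted p of 0.00168 and an adjusted p = 0.865 with an estimated correlation. The lists of MHC class II genes, monocyte genes, alternative activation, lipid handling, type 1 interferon and oxidative phosphorylation were not called by camera in this comparison. The count of 3113 fell to 1765 without the control pair of day 9, 1739 without the anti-PD-1 pair of day 9, 1570 without the anti-CTLA-4 pair of day 9 and 2030 without the anti-PD-1 pair of day 11.

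Different clusters made up much of this class in the genotypes. A cluster led by Ccl24, Nos2 and Arg1 held 27.7 percent of the class in wild-type and 3.73 percent in knockout libraries, and a cluster led by Fcrls, Cx3cr1 and Mrc1 held 2.66 and 18.2 percent. No test was run on cluster sizes, since the genes that define the clusters differed by genotype.

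The state genes of macrophages were therefore counted per library as the share of the class with a UMI, after thinning each cell to 2000 UMIs, which left out 1562 wild-type and 1209 knockout cells. Nos2 was found in 19.7 ± 10.1 percent of wild-type and 5.96 ± 2.19 percent of knockout cells (SD, n = 6), lower in 6 of 6 pairs (exact two-sided p = 0.03125, the smallest the design allows). Cx3cr1 was found in 10.6 ± 5.56 and 20.9 ± 4.93 percent, higher in 6 of 6 pairs (exact two-sided p = 0.03125). Arg1 stood at 49.7 ± 20.7 and 34.5 ± 9.55 percent (exact two-sided p = 0.09375), Cxcl9 at 52.1 ± 10.1 and 41.4 ± 6.58 percent (exact two-sided p = 0.125) and Mrc1 at 24.8 ± 3.55 and 28.5 ± 6.61 percent (exact two-sided p = 0.125). Unthinned shares were 28.4 and 10.2 percent for Nos2, 18.6 and 36.9 percent for Cx3cr1, 58.6 and 47.4 percent for Arg1, 60.5 and 51.6 percent for Cxcl9, and 42.6 and 49.0 percent for Mrc1. In T and NK cells thinned alike, which should lack most of these genes, Nos2 was found in 0.47 and 0.00 percent, Arg1 in 2.37 and 1.17 percent, Cxcl9 in 3.99 and 1.77 percent, Mrc1 in 0.80 and 0.655 percent, and Cx3cr1, which NK cells can express, in 5.4 and 3.9 percent. Median depth was 5517 UMIs in wild-type and 6952.5 in knockout macrophage/monocyte cells, and 4933.5 and 4657 in T and NK cells.

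**Figure D3:**
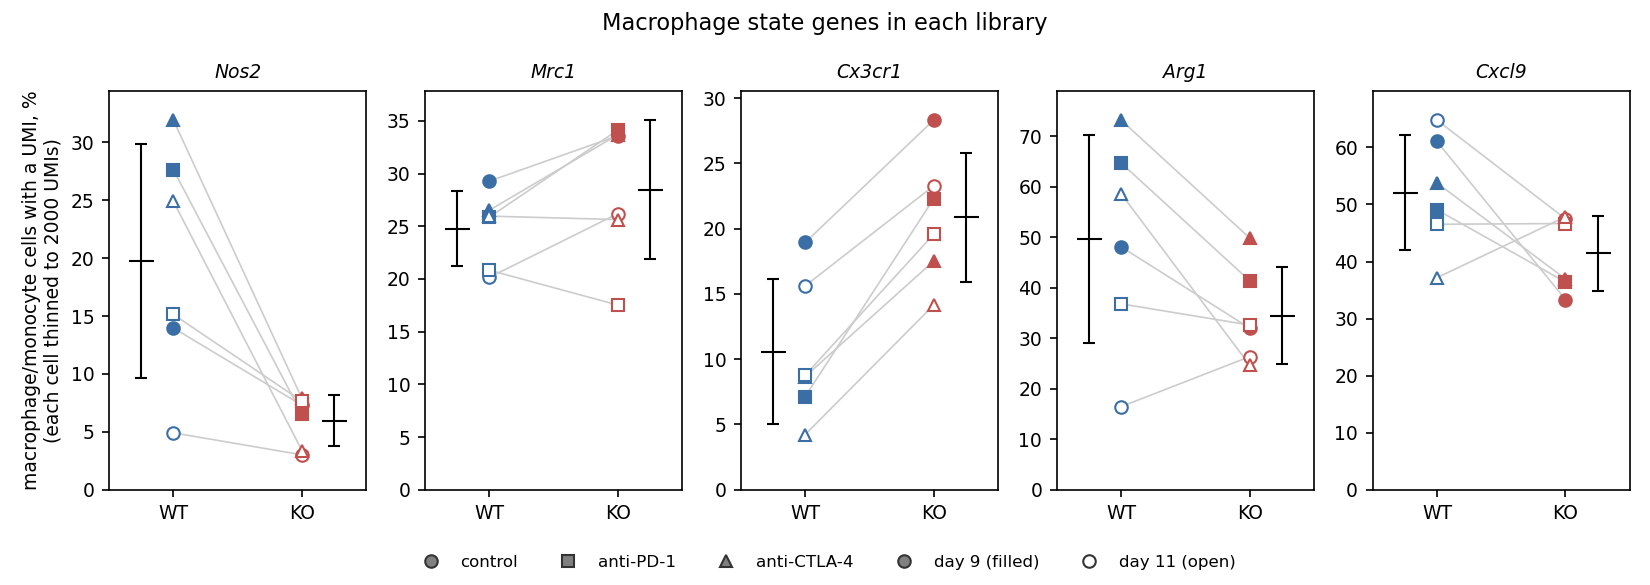
Percent of macrophage/monocyte cells with a UMI after thinning to 2000 UMIs (vertical axis) for the state genes in each library by genotype, with lines joining the libraries of 1 treatment and day. Nos2 is lower and Cx3cr1 higher in the knockout library in 6 of 6 pairs.

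CD8 T cells were compared by genotype over the same 6 pairs, with 2208 knockout and 1281 wild-type cells. The question was how the T cells that attack tumour cells differ in hosts without Bhlhe40. Knockout cells had less of the granzyme genes Gzmc to Gzmg and of Ifng, the main cytokine of these cells, but more of Gzmb, the classical granzyme, and of the chemokine Ccl5. Cluster L8, led by Ifng, was not in this class, although 87.79 percent of its cells held Cd8a and 1.67 percent Cd4. The cycling cluster L5 (Cd8a in 89.0 percent) was left out too. The changes given here, that of Ifng among them, thus cover only part of the CD8 T cells. Il10, an inhibitory cytokine gene, rose, as did Tox2, a relative of the exhaustion factor Tox, and Izumo1r, a folate receptor of T cells. The enolase gene Eno1 fell, as did the glycolysis gene Gapdh, which lies near Bhlhe40. The inhibitory receptor genes Pdcd1, Lag3, Havcr2 and Ctla4 did not pass the threshold.

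The edgeR test called 199 of 7605 genes, 89 higher and 110 lower, of which 9 were receptor segments and 14 of the 156 tested near Bhlhe40. The largest log2 rises were those of Pianp (5.19, SE 0.37), Rnf144a (3.83, SE 0.35), Il10 (3.10, SE 0.50, edgeR adjusted p = 3.11e-05, 5 of 6 pairs), Krt83 (3.00), Tox2 (2.63, SE 0.67), Klrc2 (2.60, SE 0.15), Arap3 (2.09), Klra1 (2.06, 4 of 6 pairs), Ephx1 and Izumo1r (1.87, SE 0.17). Among these Pianp, Klrc2 and Klra1 lie near Bhlhe40 on chromosome 6. Il10 had 143 counts in all, and its difference lay mostly in antibody-treated tumours. Wild-type and knockout means were 0.247 and 1.65 CPM in controls, 1.39 and 17.5 with anti-PD-1, and 0 and 27.8 with anti-CTLA-4. Within knockout tumours its rise with antibody was not past the threshold (2.21, edgeR adjusted p = 0.216). Gzmg had 103 counts in wild-type and 0 in knockout cells, at least 50.8-fold lower against a floor of 3 counts over the knockout group. Gzmd (-7.37), Gzme (-6.97), Gzmc (-4.01) and Gzmf (-3.86) fell in 6 of 6 pairs, with reads that these neighbouring genes may share. Serpine2 (-2.75, SE 0.17), Ltb4r1 (-2.03), St6gal1 (-2.01) and Gstm5 (-1.87) fell as well. Core changes were Gzmb (1.62, SE 0.26, edgeR adjusted p = 0.032), Ccl5 (0.95, SE 0.13, adjusted p = 4.9e-05) and Ifng (-0.73, SE 0.15, adjusted p = 0.00476), each in 6 of 6 pairs. Not past the threshold were Lag3 (-0.38, edgeR adjusted p = 0.0636), Havcr2 (-0.26), Ctla4 (-0.10), Pdcd1 (-0.07), Tox (0.31), Tcf7 (-0.13), Prf1 (-0.22), Tbx21 (-0.03) and Tnf (0.58).

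Of 24 T cell effector genes 5 rose and 5 fell over all genes, and 7 rose and 6 fell when adjusted over the list alone. The median log2 fold change of this list was 0.17 and its mean -0.71, with camera calling it lower (camera adjusted p = 1.18e-07; adjusted p = 0.0843 with an estimated correlation). Of 22 genes of glycolysis and hypoxia 4 fell over all genes and 7 when adjusted over the list alone, the former being Eno1 (-1.33), Gapdh (-0.49), Pgk1 (-0.53) and Ero1l (-0.73) (camera adjusted p = 1.18e-07; adjusted p = 0.469 with an estimated correlation). The list of targets reported for Bhlhe40 had 4 rises and 1 fall among 11 genes by either adjustment, a median of -0.02 and a mean of 0.45, with Il10 as its largest rise (camera adjusted p = 0.00123; adjusted p = 0.133 with an estimated correlation). Of 16 T helper 1 genes 3 rose and 4 fell over all genes, and 3 and 6 when adjusted over the list alone, with Cxcr3 (1.12) and Klrg1 (-1.58) among them (camera adjusted p = 0.0133; adjusted p = 0.185 with an estimated correlation). Klrg1 lies near Bhlhe40 on chromosome 6. The B cell transcripts Igkc (1.12) and Ighm (0.81) rose, and all 3 measured B cell markers passed when adjusted over the list alone (camera adjusted p = 0.000498; adjusted p = 0.215 with an estimated correlation). Inhibitory receptor and exhaustion genes were not called as a list. The count of 199 moved to 51 without the anti-PD-1 pair of day 11 and to 76 without the anti-CTLA-4 pair of day 11.

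NK cells, with 1681 knockout and 1458 wild-type cells in 6 pairs, were compared for the same question. Knockout NK cells had more of the chemokine genes Ccl3, Ccl4 and Xcl1, which draw other immune cells, more Gzmb, and more of proliferation genes such as Stmn1 and Mcm4. They had less of Havcr2 and Pdcd1, both inhibitory receptors, of Ctsg, a serine protease, and of Epas1, a hypoxia factor. The test called 219 of 8455 genes, 100 higher and 119 lower, including 23 of the 196 tested near Bhlhe40. The largest log2 rises were those of Pianp (7.64, SE 0.42), Muc1 (3.05), Slc6a13 (2.77), Igfbp6 (2.55), Klrb1a (2.19), Klra10 (2.03), Ccl3 (2.02, SE 0.30), Ccl4 (1.96, SE 0.12, edgeR adjusted p = 5.74e-14, 6 of 6 pairs), Klrc3 (1.68) and Ccnb2 (1.67). The largest falls were those of Ctsg (-4.52, SE 0.52), Mgat3 (-3.08), Klra3 (-2.96), Galnt18 (-2.95, 3 of 6 pairs), Spp1 (-2.65), Havcr2 (-2.52, SE 0.28, edgeR adjusted p = 9.52e-08, 5 of 6 pairs), Epas1 (-2.50), Gzme (-2.47) and Basp1 (-2.30). Pdcd1 fell by 1.54 (SE 0.20) and Gzmb rose by 1.35 (SE 0.10), while Ifng (0.25), Prf1 (-0.32), Gzma (0.01), Ccl5 (0.89) and Lag3 (-0.45, edgeR adjusted p = 0.0998) were not past the threshold. With a genotype effect per day, Pdcd1 stood at -0.305 at day 9 and -1.69 at day 11 (edgeR adjusted p = 0.916 and 3.33e-06). Havcr2 stood at -1.09 and -2.67 (edgeR adjusted p = 0.705 and 6.32e-07). Neither differed between the days past the threshold (edgeR adjusted p = 0.992 each). Both were low, with wild-type and knockout means of 18.9 and 4.72 CPM for Havcr2 and 27.7 and 12.5 CPM for Pdcd1. Klra and Klr genes may share reads here too, and those named lie near Bhlhe40 on chromosome 6.

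Of 24 cell cycle genes 8 rose in NK cells over all genes and 13 when adjusted over the list alone, with Stmn1 (1.02) and Mcm4 (0.85) (camera adjusted p = 1.47e-11; adjusted p = 0.0688 with an estimated correlation). The list of inflammatory macrophages had 2 rises among 9 genes, 3 when adjusted over the list alone, and its members over all genes were the chemokines Ccl3 and Ccl4, joined by Ccl5 over the list alone, all of which NK cells make themselves (camera adjusted p = 4.6e-11; adjusted p = 0.0176 with an estimated correlation). Of 22 inhibitory receptor and exhaustion genes 3 fell over all genes and 11 when adjusted over the list alone, where 1 also rose (camera adjusted p = 1.34e-05; adjusted p = 0.0688 with an estimated correlation). Slc16a3 (-1.18), Gapdh (-0.61) and Eno1 (-0.71) were among 4 of 23 glycolysis genes that fell by either adjustment (camera adjusted p = 0.000376; adjusted p = 0.494 with an estimated correlation). The clusters of this class were filled differently by genotype, without a test. A cluster led by Gzma, Klra4 and Klrb1a held 57.6 percent of NK cells in wild-type and 74.8 percent in knockout libraries, a cluster led by Gzmc, Car2 and Gzma 22.4 and 12.1 percent, and a cluster led by Gzmd to Gzmg 7.21 and 0.46 percent. Without the anti-PD-1 pair of day 11 the count of 219 fell to 81.

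Conventional CD4 T cells reached 20 cells in both libraries of 3 pairs, so that 6 libraries were compared. Knockout cells had more Il21, a cytokine that helps B and CD8 T cells, more of the cytokine Tnf, the chemokine genes Ccl3 and Ccl1, and Izumo1r, and less of the survival gene Bcl2, the glucose transporter gene Slc2a3, and the early response genes Fosb and Nr4a3. Of 5883 genes 70 were called, 41 higher and 29 lower, including 7 of the 118 tested near Bhlhe40, where Pianp and Klrc2 lie. Log2 rises included Pianp (4.55), Rnf144a (3.67), Klrc2 (3.28), Izumo1r (2.93, SE 0.26, edgeR adjusted p = 4.14e-08), Ccl3 (2.61), Il21 (2.31, SE 0.57), Abcb9 (2.26), Ccl1 (1.79) and Tnf (1.18, SE 0.28). Falls included Gstm5 (-3.87, SE 0.54), Bhlhe40 (-2.95), Mmp9 (-2.61), Fosb (-2.21), Ero1l (-1.80), Bcl2 (-1.65), Slc2a3 (-1.46) and Nr4a3 (-1.39). Csf2 (-1.42), Il10 (1.26), Ifng (0.58), Lag3 (0.83) and Il2 (-0.05) were not past the threshold. Over all libraries, those under 20 cells included, mean Gzmb was 149 ± 139 CPM in wild-type and 1074 ± 584 CPM in knockout (SD, n = 6 each). Mean Ccl5 was 220 ± 303 and 603 ± 174 CPM in the same order. Of 22 effector genes 4 rose over all genes and 5 when adjusted over the list alone (camera adjusted p = 6.94e-10; adjusted p = 0.308 with an estimated correlation). Of 23 dissociation stress genes 2 fell over all genes, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.47e-06; adjusted p = 0.317 with an estimated correlation). The count of 70 fell to 13 without the control pair of day 11 and to 26 without the anti-CTLA-4 pair of day 11.

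Treg cells were compared in 5 pairs, and 3 of 3793 genes were called, each in 5 of 5 pairs. Of these 2, Pianp and Bhlhe40 itself, were among the 80 tested near Bhlhe40. Pianp rose by 6.03 log2 units (SE 0.73), Bhlhe40 fell by 3.02 (SE 0.42), and Il7r, the receptor for interleukin 7, fell by 1.14 (SE 0.17, edgeR adjusted p = 0.00022). Foxp3, the factor that defines these cells, stood at -0.01. Il10 (0.80), Cxcr6 (0.63), Ctla4 (0.40) and Gzma (-0.99) were not past the threshold, each moving one way in 4 of 5 pairs. Of 15 naive and memory T cell genes Il7r alone fell over all genes, and 3 fell when adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.386 with an estimated correlation). Leaving out single pairs gave 8 genes without the control pair of day 9, 6 without the anti-PD-1 pair of day 9, 16 without the control pair of day 11 and 7 without the anti-CTLA-4 pair of day 11.

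Treatment with either checkpoint antibody was compared with the isotype control within each genotype, to ask how the cells respond to checkpoint therapy with and without Bhlhe40. In wild-type macrophage/monocyte cells edgeR called 55 of 13078 genes, 21 higher and 34 lower. DESeq2 called 534, and edgeR called 0 without the day term, 1 with anti-PD-1 alone and 278 with anti-CTLA-4 alone. Hbegf, a growth factor, and Src, a kinase, rose, as did Cd1d1, which presents lipids, while Xcr1, a chemokine receptor of cross-presenting dendritic cells, and the mitosis genes Prc1, Cenpe and Diaph3 fell. The largest log2 rises were those of Fam169b (2.18), Tnfrsf26 (1.76), Hbegf (1.61), Src (1.46), Smpd5 (1.41), Fcor (1.37), Ms4a8a (1.30), Rhou (1.285) and Cd1d1 (1.19). The largest falls were those of Xcr1 (-2.48, SE 0.39), Tespa1, Ankle1 (-1.97), Abcb4 (-1.76), Neurl1a (-1.55), Prc1 (-1.45, SE 0.20), Cdca2 (-1.39), Bank1 (-1.37) and Zwilch (-1.36). Each of these moved one way in all 4 comparisons of an antibody with the control of the same day. Both antibodies of a day share 1 control library, and the genes were picked from the same libraries, so the 4 comparisons are not independent. Of 40 cell cycle genes 2 fell over all genes and 39 when adjusted over the list alone (median log2 -1.01; camera adjusted p = 4.45e-49; adjusted p = 0.179 with an estimated correlation). Of 23 genes of lipid handling none passed over all genes and 9 rose when adjusted over the list alone (camera adjusted p = 8.47e-10; adjusted p = 0.179 with an estimated correlation), and of 27 glycolysis genes 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.63e-12; adjusted p = 0.262 with an estimated correlation). Nos2 (1.88, edgeR adjusted p = 0.105), Cx3cr1 (-1.16, adjusted p = 0.0527) and Cd274 (0.86, adjusted p = 0.0652) were not past the threshold.

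In knockout macrophage/monocyte cells edgeR called 0 genes for antibody against control, with 572 at an unadjusted p under 0.05 and 0 by DESeq2. The cell cycle list had a median of -0.28 (camera adjusted p = 3.24e-09; adjusted p = 0.598 with an estimated correlation). The difference between the genotypes in antibody effect, which tests whether the responses differ, gave 0 genes by edgeR, 766 at an unadjusted p under 0.05 and 20 by DESeq2. In that interaction the B cell list, with Igkc and Ighm, had 4 of 6 members higher when adjusted over the list alone (camera adjusted p = 2.79e-10; adjusted p = 0.028 with an estimated correlation), and the cell cycle list had a median of 0.75 (camera adjusted p = 7.33e-24; adjusted p = 0.243 with an estimated correlation). Anti-CTLA-4 against anti-PD-1 gave 0 genes by edgeR, 552 at an unadjusted p under 0.05 and 11 by DESeq2, with haemoglobin genes lower (list median -5.92, 4 of 4 when adjusted over the list alone; camera adjusted p = 5.12e-52; adjusted p = 0.0125 with an estimated correlation). The count of 55 in wild-type cells moved to 28 without the wild-type control of day 9, 7 without wild-type anti-PD-1 of day 9, 25 without knockout anti-PD-1 of day 9, 708 without wild-type anti-CTLA-4 of day 9, 0 without the wild-type control of day 11, 190 without wild-type anti-PD-1 of day 11, 25 without knockout anti-PD-1 of day 11 and 6 without wild-type anti-CTLA-4 of day 11.

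CD8 T cells were compared with antibody in the same way, and many of the called genes were receptor segments, which differ with the clones present. In wild-type cells edgeR called 6 of 7605 genes, with Serpine2 higher (1.03), Serpinb1a lower (-1.44) and 4 receptor segments. In knockout cells it called 6, with Serpinb9b, a protease inhibitor gene, lower (-2.01, SE 0.29) and 5 receptor segments. The antibody effect differed by genotype for 3 genes, namely Serpinb9b (-2.79, SE 0.41, edgeR adjusted p = 0.000123, 4 of 4 same-day comparisons) and 2 receptor segments. Those comparisons share the control libraries of their day and are not independent. Between anti-CTLA-4 and anti-PD-1 11 genes were called, 4 of them receptor segments. Tox, a factor of exhausted T cells, was lower with anti-CTLA-4 (-1.74, SE 0.23, edgeR adjusted p = 7.27e-06, 4 of 4 comparisons). Cd4 (1.98), Serpinb1a (1.33), Hspa1a (1.19), Rora (0.97) and Emb (0.91) were higher with anti-CTLA-4. Cd4, Rora and Serpinb1a were also leading genes of the cluster of conventional CD4 T cells. Cd4 had 145 counts in the CD8 class. It was found in 7.26 percent of cells of the CD8 cluster L12, 0.5 percent of L1 and 1.89 percent of L2. CD4 T cells within the class thus stay open as a source of the rises of Cd4, Rora and Serpinb1a. Glycolysis genes in wild-type cells had 4 of 22 members higher when adjusted over the list alone (camera adjusted p = 5.86e-08; adjusted p = 0.241 with an estimated correlation), and type 1 interferon genes in knockout cells had 5 of 24 (camera adjusted p = 1.13e-11; adjusted p = 0.354 with an estimated correlation). On leaving out single libraries the counts ranged from 1 to 48 in wild-type cells, 0 to 43 in knockout cells, 0 to 32 in the interaction and 1 to 35 between the antibodies.

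Conventional CD4 T cells could be compared with antibody in knockout tumours, where 14 of 5671 genes were called, 1 higher and 13 lower, 6 of them receptor segments. Knockout anti-PD-1 was 1 library there, that of day 11 with 57 cells, since that of day 9 held 17, and it was assumed to vary like the other groups. The same-day comparisons of day 11 share 1 control library. Csf2, which feeds myeloid cells, fell in 3 of 3 same-day comparisons (edgeR adjusted p = 4.51e-06). It had 61 counts in the control, 6 with anti-CTLA-4 and 0 with anti-PD-1, at least 6.67-fold lower with anti-PD-1 against a floor of 3 counts over the group. Il5 fell in 2 of 3 comparisons, with 40 counts in the control, 5 with anti-CTLA-4 and 0 with anti-PD-1, at least 4.38-fold lower with anti-PD-1, and its fitted direction turned without the knockout control of day 11. Il4 fell in 3 of 3, from 35 counts to 3 with each antibody, and Ifng (-1.43) fell in 3 of 3. Hspa1a (-1.64) and Hspa1b (-1.83), which respond to stress, fell as well. Cst3 was called higher, but stood at 198 CPM in the control, 193 with anti-CTLA-4 and 775 in the lone anti-PD-1 library, so that the call rests on that library. With anti-CTLA-4 in wild-type tumours 19 genes were called, 10 higher and 9 lower, with only 1 same-day comparison. The wild-type control was 1 library, that of day 11 with 72 cells, since that of day 9 held 14, and it too was assumed to vary like the others. Il5 had 53 counts with anti-CTLA-4 and 0 in the control, at least 7.13-fold higher against a floor of 3 counts in the control. Csf2 (3.52) and Il1rl1, the receptor for interleukin 33 (2.79), rose, from 5 and 6 counts in the control, and Il4 and Gzma from 2 counts each. Cd8b1, a marker of CD8 T cells, rose with them, from 1 count in the control to 49 with anti-CTLA-4. Without wild-type anti-CTLA-4 of day 11 the direction of Gzma turned. Nr4a2 (-2.70) and Gimap7 fell. With the same lone control, the anti-CTLA-4 effect differed by genotype for 11 genes, among them Csf2 (-7.28, SE 0.86, edgeR adjusted p = 4.6e-07), Il1rl1 (-5.00) and Furin (-2.02). Il4, Il5, Gzma and Cd8a were lower too, with 0 to 2 counts in that control, and Gzma turned without wild-type anti-CTLA-4 of day 11. DESeq2 called 0 genes in each of these 3 comparisons, and on leaving out single libraries edgeR called 8 to 30, 3 to 51 and 2 to 26 genes. Most counts of Csf2, Il4, Il5 and Gzma came from wild-type anti-CTLA-4 of day 11 and from the knockout control of day 11.

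Day 11 was compared with day 9 within 6 pairs of the same genotype and treatment. In macrophage/monocyte cells MHC class II genes such as Cd74 and H2-Aa, which present antigen, Apoe, and the B cell chemokine Cxcl13 rose, while the histone genes Hist1h3b and Hist1h3c, most of the cell cycle genes listed, the neutrophil gene S100a9 and Nos2 fell. The edgeR test called 5296 of 13078 genes, 2715 higher and 2581 lower at day 11. Large log2 rises were those of H2-M2 (3.80), C6 (3.69), Cxcl13 (3.48, 4 of 6 pairs), Hsd17b14 (3.09), Ly6g6e (3.06), Cd209f (2.99) and S1pr5 (2.92). Large falls were those of Cspg4 (-3.32), S100a9 (-3.25, 5 of 6 pairs), Hist1h3b (-3.19), Aldh1a3 (-3.18), Hist1h3c (-3.02) and Acta1 (-2.77). Core changes included Apoe (1.15, SE 0.14), H2-Ab1 (1.09, SE 0.14), C1qa (0.73), Nos2 (-0.97, SE 0.27, edgeR adjusted p = 0.0261), Ccr2 (-0.66), Mrc1 (-0.59) and Cx3cr1 (-0.48). Of 40 cell cycle genes 31 fell over all genes and 34 when adjusted over the list alone (camera adjusted p = 6.4e-17; adjusted p = 0.494 with an estimated correlation). Of 15 MHC class II genes 8 rose, and 9 when adjusted over the list alone, with Cd74 (1.41), H2-Aa (1.15) and H2-Eb1 (1.14) (camera adjusted p = 0.000315; adjusted p = 0.655 with an estimated correlation). Of 23 genes of lipid handling and lysosomes 14 rose by either adjustment, with Ctsb (0.64) and Abcg1 (0.83) (camera adjusted p = 0.000107; adjusted p = 0.347 with an estimated correlation). T cell genes such as Cd3g (1.39) also rose in this class, with 9 of 14 markers higher by either adjustment (camera adjusted p = 0.000418; adjusted p = 0.653 with an estimated correlation), and 12 of 13 mitochondrially encoded genes rose by either adjustment (camera adjusted p = 1.71e-13; adjusted p = 0.347 with an estimated correlation).

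In CD8 T cells 1136 of 7605 genes were called by day, 666 higher and 470 lower at day 11, including 14 receptor segments. Areg, a growth factor (2.74, 5 of 6 pairs), Chka (2.48), mt-Atp8 (2.21), the inhibitory receptor gene Pvrig (1.98) and Gstm5 (1.88) rose, and Arg1 (-3.06), Il6ra (-3.05), Tnfsf8 (-2.57), Cxcl10 (-2.46), Cd40lg (-2.33) and Ramp3 (-2.17) fell. Arg1 and Cxcl10 stood at 1578 and 755 CPM in wild-type macrophage/monocyte cells. The macrophage gene C1qa was found in 8.29 percent of cells of the CD8 cluster L1. RNA of macrophages in these droplets stays open as a source of both falls, with as few as 31 CD8 T cells in a day 9 library. Pdcd1 (0.64, SE 0.12, edgeR adjusted p = 9.84e-05, n = 6 pairs), Ccl5 (0.85), Tbx21 (0.68), Cxcr6 (0.47) and Tnf (1.20, SE 0.39) rose, and Icos (-0.60, SE 0.11) fell. Of 24 type 1 interferon genes 10 fell and 1 rose over all genes, and 16 and 1 when adjusted over the list alone, with Slfn5 (-1.89), Isg15 (-0.80) and Ifi204 (-2.08) (camera adjusted p = 2.57e-06; adjusted p = 0.474 with an estimated correlation). Of 13 mitochondrially encoded genes 12 rose by either adjustment (camera adjusted p = 1.34e-39; adjusted p = 0.115 with an estimated correlation). Without the knockout anti-PD-1 pair the count fell to 731. With the unassigned T cell cluster L8 included it was 1840, and Areg (-0.41) and Tnf (-0.84) then had the other sign.

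The shares of 13 cell classes among the sorted CD45-positive cells left after the filters and doublet removal were compared as well. Macrophage/monocyte cells made up 58.8 ± 5.77 percent of wild-type and 60.7 ± 7.39 percent of knockout libraries (SD, n = 6). CD8 T cells made up 3.62 ± 3.15 and 5.05 ± 4.57 percent, NK cells 4.29 ± 2.35 and 3.99 ± 3.55 percent, Treg cells 1.29 ± 0.83 and 0.98 ± 0.922 percent, and neutrophils 3.14 ± 3.02 and 4.37 ± 3.10 percent. Clusters L8 and L5, with Cd8a in 87.79 and 89.0 percent of their cells, were not counted as CD8 T cells. By edgeR 0 classes differed by genotype, 0 at an unadjusted p under 0.05, and mature dendritic cells had the lowest exact p, being lower in 6 of 6 knockout libraries (0.861 ± 0.158 and 0.683 ± 0.216 percent; exact two-sided p = 0.03125; edgeR adjusted p = 0.461). With antibody 0 classes changed in either genotype and 0 differed in the interaction by edgeR, with 1 class in wild-type, 2 in knockout tumours and 1 in the interaction at an unadjusted p under 0.05. Conventional dendritic cells of type 2 in knockout tumours came nearest with a log2 change of -0.65 (edgeR adjusted p = 0.105). Cells in clusters left without a name made up 16.7 percent of wild-type and 12.3 percent of knockout libraries. Their low-UMI cluster held 12.7 to 27.9 percent of the kept cells at day 9 and 1.90 to 5.87 percent at day 11, which can shift any share set against all cells.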

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

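The interaction test in CD8 T cells was planned before any result was seen, and the anti-CTLA-4 interaction in conventional CD4 T cells was added after the cells had been counted. Conventional CD4 T cells made up 3.22 percent of the wild-type anti-CTLA-4 library of day 11, with the next wild-type library at 1.10 percent. Neutrophils made up 8.89 percent of the same library, with the next at 3.28 percent. Fibroblast-like or tumour-like cells made up 2.86 percent of the knockout control library of day 11, with the next knockout library at 1.26 percent. These stood out by Dixon's test, in which about 5 percent of groups would do so by chance, and 45 groups were checked.

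The antibody effect differed by genotype for 3 genes in CD8 T cells and, with anti-CTLA-4, for 11 genes in conventional CD4 T cells. The cytokine genes Csf2, Il4 and Il5 among those 11 owe most of their counts to wild-type anti-CTLA-4 and knockout control of day 11, the first of which also has the outlying CD4 share. The wild-type control of that CD4 comparison was 1 library. Group size and single libraries remain open as sources of these calls.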

How the results depend on the processing

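Fits without the region around Bhlhe40, on single days, on thinned counts, with clusters L8, L5 or the low-UMI clusters, on single antibodies, without receptor segments and without the length trend were chosen after results were seen, and the other alternatives before, and the cause was not tested for any count that moved. Called genes are given below by edgeR unless DESeq2 is named. By genotype in macrophage/monocyte cells (3113) antibody-treated pairs alone gave 1893 and day 11 alone 11, against 3953 at day 9 alone (359 and 2257 in a fit of both days), and leaving out pairs gave 1570 to 3319. By antibody in wild-type macrophage/monocyte cells (55) DESeq2 gave 534, no count filter 219, cells of at least 2000 UMIs 85, kept doublets 90, macrophage-like clusters alone 109, low-UMI clusters included 23, no day term 0, anti-PD-1 alone 1 and anti-CTLA-4 alone 278, and leaving out libraries gave 0 to 708. In knockout cells leaving out libraries gave 0 to 1. For the interaction in that class (0) DESeq2 gave 20 and no filter 1, with 0 to 24 on leaving out libraries (24 without wild-type anti-CTLA-4 of day 9). Between the antibodies DESeq2 gave 11, with 0 to 4. By day in that class leaving out pairs gave 3975 to 5491. By genotype in CD8 T cells (199) antibody-treated pairs alone gave 315, day 9 alone 55, day 11 alone 85, and clusters L8 and L5 included 130, with 51 to 259 on leaving out pairs. By day in CD8 T cells (1136) cluster L8 included gave 1840, with 731 to 1090. By antibody in wild-type CD8 T cells (6) DESeq2 gave 0, no filter 16, cluster L8 included 12, segments left out 1, no day term 0 and anti-CTLA-4 alone 16. Without wild-type control of day 9 the count was 48, and it was 17 without knockout control, 13 without wild-type anti-PD-1, 19 without knockout anti-PD-1, 33 without wild-type anti-CTLA-4 and 19 without knockout anti-CTLA-4 of that day. Without wild-type control or wild-type anti-PD-1 of day 11 it was 3, without knockout anti-PD-1 2 and without wild-type anti-CTLA-4 1. By antibody in knockout CD8 T cells (6) DESeq2 gave 1, no filter 26, segments left out 1, no day term 0 and anti-PD-1 alone 14. Leaving out day 9 libraries gave 43 (wild-type control), 32 (knockout control), 14 (wild-type anti-PD-1), 26 (knockout anti-PD-1), 28 (wild-type anti-CTLA-4) and 30 (knockout anti-CTLA-4), and leaving out day 11 libraries 0 (knockout control) and 2 (knockout anti-CTLA-4). For the CD8 interaction (3) DESeq2 gave 1, no filter 13, cluster L8 included 5, segments left out 1 and no day term 0. The same day 9 libraries, left out in that order, gave 32, 20, 6, 14, 15 and 19, and the day 11 controls 1 (wild-type) and 0 (knockout). Between the antibodies in CD8 T cells (11) DESeq2 gave 4, no filter 18, cluster L8 included 6, segments left out 7 and no day term 1. Leaving out day 9 libraries gave 27 (wild-type control), 23 (knockout control), 24 (knockout anti-PD-1), 35 (wild-type anti-CTLA-4) and 24 (knockout anti-CTLA-4), and leaving out day 11 libraries 7 (knockout control), 1 (wild-type anti-PD-1), 1 (knockout anti-PD-1), 1 (wild-type anti-CTLA-4) and 4 (knockout anti-CTLA-4). By genotype in conventional CD4 T cells (70) DESeq2 gave 25, no filter 116 and antibody-treated pairs alone 13, with 13 to 92 on leaving out pairs. By antibody in knockout CD4 T cells (14) DESeq2 gave 0, segments left out 8, no day term 1 and anti-CTLA-4 alone 8, with 30 without knockout control and 22 without knockout anti-CTLA-4 of day 9, and 24 without wild-type control and 8 without knockout anti-CTLA-4 of day 11. With anti-CTLA-4 in wild-type CD4 T cells (19) DESeq2 gave 0, segments left out 10 and no day term 1, with 51 without knockout control and 33 without wild-type anti-CTLA-4 of day 9, and 7 and 3 without the same libraries of day 11. For that interaction (11) DESeq2 gave 0, no filter 18 and no day term 2, with 26, 17 and 19 without knockout control, wild-type anti-CTLA-4 and knockout anti-CTLA-4 of day 9, and 20, 2 and 6 without those of day 11. By genotype in Treg cells (3) no filter gave 19, deeper cells 6, kept doublets 5, additive terms 6, antibody-treated pairs alone 36, day 11 alone 6 and the region left out 1, with 2 to 16 on leaving out pairs. By genotype in NK cells (219) DESeq2 gave 138, day 9 alone 79 and day 11 alone 67, with 81 to 321. Among class shares (0) the exact permutation gave 1 by genotype at an unadjusted p under 0.05, which is not the adjusted threshold of the 0. With low-UMI clusters included 1 was called with antibody in knockout tumours. Leaving out the anti-CTLA-4 pair of day 11 gave 1 by genotype, wild-type anti-CTLA-4 of day 9 gave 1 in wild-type tumours and 1 in the interaction, and knockout control of day 9 gave 3 in knockout tumours. Of 136 list calls by camera 3 held with an estimated correlation, and fry called 30 of all 435 list tests as moving one way. Signs reversed for 4 named genes, for Gzma in both of its comparisons. With cluster L8 included Areg (-0.41) and Tnf (-0.84) had the other sign by day in CD8 T cells. On leaving out libraries the fitted log2 fold change of Il5 by antibody in knockout CD4 T cells ranged from -5.58 to 1.29 (without knockout control of day 11). Gzma ranged from 3.94 to -2.33 with anti-CTLA-4 in wild-type CD4 T cells and from -6.20 to 0.49 in the interaction, with both reversals on leaving out wild-type anti-CTLA-4 of day 11. Of 8450 alternatives for named genes 7429 kept their label, 305 moved, 92 were stronger and 619 weaker. Of 846 for shares 771 kept theirs, 68 moved and 7 were stronger. All 20 for the state genes of macrophages kept theirs. The antibody comparison in wild-type CD4 T cells and its interaction with both antibodies could not be fitted, since no wild-type anti-PD-1 library held 20 cells of the class. The labels give no replicate numbers, and the pairs and blocks are libraries of the same treatment and day.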

Other observations

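The splits, the depth check, the check on RNA of other cells the odds ratio of genes near Bhlhe40 and the check on mitochondrially encoded genes by day were chosen after results were seen, while the checks without Klr and Clec genes, in the day comparison, with the length trend and on Lars2 and Gm42418 were written down before they were run.

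In macrophage/monocyte, CD8 T and NK cells 34 of the 7162 genes tested in all 3 classes were called by genotype in each, and 31 moved in the same direction, 8 higher and 23 lower. Of the 23 falls 6 were ribosomal protein genes (Rpl37a, Rpl38, Rpl41, Rps21, Rps28 and Rps29). Of 14 ribosomal protein genes with transcripts under 500 bases 6, 4 and 5 were called lower and 0 higher in the 3 classes. Of 78, 72 and 74 longer ones 5, 6 and 4 were called lower and 20, 0 and 0 higher. A trend with transcript length thus stays open among the shared falls. The others included Eno1 and Gapdh of glycolysis, of which Gapdh lies near Bhlhe40, Hif1a (-0.47, -0.43 and -0.92), which drives the response to low oxygen, the granzyme gene Gzme, the adhesion gene Pecam1 and, as a rise, the chemokine receptor gene Cxcr3. The classes come from the same libraries, so that these counts are not independent. In NK and CD8 T cells Gzmb rose while Gzme fell, although both are granzyme genes of like sequence.

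Genes within 25 Mb of Bhlhe40 were called by genotype more often than others, with an odds ratio of 3.60 in CD8 T cells (Fisher's exact two-sided p = 0.00019) and 1.46 in macrophage/monocyte cells (exact p = 0.00467). In CD8 T and NK cells the excess lay mostly at 120 to 140 Mb of chromosome 6, while Bhlhe40 lies in the interval from 100 Mb. Calls were 8 of 59 and 12 of 72 genes from 120 Mb and 2 of 20 and 6 of 25 from 130 Mb, against 0 of 32 and 1 of 40 from 110 Mb, 1 of 7 and 1 of 10 from 100 Mb (Bhlhe40 left out), and 0 of 17 and 1 of 20 from 90 Mb. Variants of another strain kept around a targeted gene stay open, since gene counts gave no test of them apart from this odds ratio. Klr and Clec families alone are argued against by an odds ratio of 2.81 in NK cells without them (Fisher's exact p = 0.00335). With them it was 5.23, and the calls near Bhlhe40 were 22 of 195 genes with and 11 of 172 without them. These families thus carry part of the excess in NK cells. A region that is called in any comparison is argued against by 1.15 for day in CD8 T cells (exact p = 0.495). Pianp, C1rb, Klra3 and Clec9a, among the largest changes, lie there, as do the other Klr and Klra genes named by genotype. Their link to the loss of Bhlhe40 itself thus stays open. Without the region 3026 genes were still called in macrophage/monocyte cells.

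The genotype difference of macrophage/monocyte cells might come from deeper knockout libraries, from RNA of other cells or from a trend with transcript length. After thinning the summed counts of each pair to the smaller total 89.2 percent of the calls remained in the same direction, which argues against the total depth of the libraries. Depth per cell was not matched in that fit and stays open. Of the called genes 10.8 percent were at least 4 times as abundant in fibroblast-like or tumour-like clusters or in T and NK cells, which argues against these cells as the main source. Neutrophils, dendritic cells and B cells were not in that check, so that RNA of them stays open. Genes enriched in fibroblast-like or tumour-like clusters made up 13.4 percent of the rises, 2.74 percent of the falls and 9.83 percent of all tested genes, so that RNA of these cells stays open for part of the rises. Timp1, Gzme and Gzmg may belong to the part from other cells. With the length trend removed 75.8 percent remained, so that the trend stays open for the rest. Swapping genotypes within pairs called as many genes as the real grouping in 1 of 32 splits, the real one, with 3113 genes against at most 8 in any other.

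In CD8 T cells the real grouping by genotype was again 1 of 32 splits with 199 genes (highest other 36), and in NK cells 1 of 32 with 219 (highest other 55). By day it was 1 of 32 with 5296 genes in macrophage/monocyte cells (highest other 4) and 1 of 32 with 1136 in CD8 T cells (highest other 14). The splits were too few to tell in conventional CD4 T cells (1 of 4 splits, 70 genes, highest other 6). In Treg cells 4 of 16 splits, the real one among them, called at least the 3 genes of the real grouping (highest other 7). The Treg count was thus no larger than other groupings of the same libraries gave.

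Lars2 and Gm42418 were lower at day 11 in all 6 pairs in 5 of 5 classes, which is in line with a property of the library or preparation shared by all cells. In macrophage/monocyte cells Lars2 went from 4544 to 1648 CPM (n = 6 libraries per day). Mitochondrially encoded genes were higher at day 11 in 6 of 6 pairs in macrophage/monocyte, CD8 T and NK cells (19607 and 29639 CPM in the first), higher in 5 of 6 pairs in conventional dendritic cells of type 2, and lower in 6 of 6 pairs in neutrophils. The mean log2 ratio in neutrophils was -0.428 (SD 0.284, 13807 and 10163 CPM), which argues against a property shared by all cells for these genes. The low-UMI cluster held a mean of 18.9 percent of kept cells at day 9 and 3.39 percent at day 11. The labels do not say whether the days were prepared separately, so that tumour age and handling both stay open.

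The genotype effect did not differ by day past the threshold for any gene by edgeR, with 0 genes in macrophage/monocyte cells, 0 in CD8 T cells and 0 in NK cells (1242, 355 and 404 at an unadjusted p under 0.05). Haemoglobin genes in macrophage/monocyte cells summed to 64.95 CPM in wild-type anti-PD-1 of day 9, 58.4 CPM in knockout anti-PD-1 of day 9 and 21.4 CPM in the knockout control of day 9.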
